A study of Mus musculus with 12 samples.

How the data were processed

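Expression was measured on a single-colour whole-transcript mouse array in 12 samples of embryonic fibroblasts, 3 each of WT undifferentiated, WT differentiated, D1D2KO undifferentiated and D1D2KO differentiated cells. Groups and replicate numbers came from the sample titles. The deposited table held 35556 probe sets, and its values, between 1.15 and 14.17, were taken as log2 array signals normalized between arrays by the authors. The base is inferred from the values, since the highest exceeds 11.09, the natural log of the largest value of a 16-bit scanner, and array summaries are usually on the log2 scale. How the authors summarised and normalized the scans was not given in the sources used here, nor were detection calls or scanner files, so a signal near the lowest values cannot be told from background. Column medians lay between 5.61 and 5.69, the sorted columns differed by up to 0.533, and 0 columns were identical, so the values had not been forced to 1 common distribution.

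Probe sets were named from the platform annotation. Of them 21789 had 1 gene, 1621 had several and 12146 had none listed, and those of the last 2 kinds were left out of the gene-level tests. Of the 21789 gene identifiers 21698 were found in a table of RefSeq genes on GRCm38.p6, which changed 0 symbols and was used for names and for the order of neighbouring genes only, since the build behind the annotation was not given. For 999 genes with more than 1 probe set the one with the highest mean over all samples was used, without regard to group, which left 19938 genes. No genes were removed for low signal.

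All 12 samples entered 1 linear model with the 4 group means, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and 5 contrasts were tested, two-sided. They were differentiation in WT, differentiation in D1D2KO, D1D2KO against WT in each state, and the difference between the 2 differentiation responses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 19938 genes, without a minimum fold change. On simulated data with the measured gene means and residual standard deviations and normal noise, the test recovered 68.7% of changes of 0.5 log2 in WT differentiation and 100% of changes of 1, while for the difference in response it recovered 19.4% of changes of 0.5 and 91.0% of changes of 1. A missing call of a small difference in response therefore says little. Each run changed 67 genes by 0.5 and 67 by 1, whereas 6794 genes were called in the real WT differentiation. More changed genes loosen the adjusted threshold, so the 68.7% need not hold for that comparison.

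Of 28 gene lists written beforehand, 27 had at least 5 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. The Benjamini-Hochberg adjustment ran over the 27 lists of a contrast. The remaining list, of sex-linked genes, had 4 measured members and is given gene by gene. Camera was repeated with an estimated correlation, and the self-contained test fry was run as well. On simulated data with independent genes camera called a list in 0 of 20 draws without a change and found a shifted list in 20 of 20 draws. The estimated correlation reached 0.680 in the glucose list, so these draws say nothing about false calls among correlated genes. Lists of smooth muscle, cardiac muscle and hypoxia-responsive genes, and of X-linked genes that escape inactivation, were written after the genotype differences had been seen. The first 3 of these, and the members of the 2 muscle lists that had not been looked at before, made 5 added lists, which were adjusted among themselves. The list of escaping genes had 4 members and was not tested as a list.

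Named genes followed a rule set beforehand. It took Dgat1 and Dgat2, then for each contrast the 10 genes with the largest rise and the 10 with the largest fall among called genes whose samples did not overlap between the 2 groups. From each list it took up to 4 called members with the largest change and up to 2 uncalled members with the highest signal. Predicted genes could be counted without a name. Of the genes the rule gives, those whose call ended when 1 sample was left out are named with that sample or not named. Single genes outside the rule, in the closing section, were chosen after their values were seen.

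The alternatives were centring each array, quantile normalization, genes above the median signal, the mean of a gene's probe sets, all probe sets, only the 2 groups compared, trended and robust eBayes, array weights, a 2-fold minimum, the replicate number as a block and leaving out each sample in turn. A linear-scale pseudocount did not apply to log2 values. All 3 pairs with equal replicate numbers had correlations of their deviations above 0.1 only between undifferentiated and differentiated D1D2KO cells, from 0.101 to 0.176, against -0.147 to 0.0522 for unequal numbers. By this rule the number was taken to pair samples in that comparison alone. Between undifferentiated WT and D1D2KO cells 2 of 3 equal numbers exceeded 0.1 (highest 0.184, against at most 0.0424 for unequal numbers), so variation shared by number is not excluded there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.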

Results

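Fibroblasts grown from mouse embryos at embryonic day 14 were profiled on 12 expression arrays, in 4 groups of 3 samples. The cells were wild type (WT) or D1D2KO, cells deficient in the diacylglycerol acyltransferases DGAT1 and DGAT2, the enzymes that attach the last fatty acid in triacylglycerol synthesis. Each genotype was taken undifferentiated or after conversion to adipocytes. For conversion, confluent cells received insulin (5 µg/ml), troglitazone (15 µM), dexamethasone (1 µM) and isobutylmethylxanthine (500 µM), then insulin with troglitazone, then plain medium. Samples of 1 group had Pearson correlations of 0.993 to 0.997 across 19938 genes. Correlations between the states ran from 0.951 to 0.971, and those between the genotypes from 0.990 to 0.995 in undifferentiated and from 0.986 to 0.993 in differentiated cells. The main principal component held 74.2% of the variance and separated the states, and the next, with 11.7%, separated the genotypes. On the main component differentiated samples scored 41.2 to 45.1 in D1D2KO and 26.2 to 35.0 in WT. The undifferentiated samples of both genotypes lay between -39.1 and -35.8. Differentiated D1D2KO samples thus lay further along the component that separated the states, and the extent of conversion in each genotype was not tested. The number of arrays limits the precision of every comparison. The series calls the samples biological replicates without saying which embryo or culture each came from, so p-values measure the spread between these samples. Differences are on the log2 scale, with the standard error (SE) of the limma fit and 3 samples per group, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05.

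The targeted genes were compared between the genotypes by their array signals. Both were lower in D1D2KO cells in each state, and both still rose when D1D2KO cells differentiated. In undifferentiated cells the difference between D1D2KO and WT was -1.34 (SE 0.11) for Dgat1, which left 39.4% of the WT signal (limma, Benjamini-Hochberg adjusted p = 6.98e-07). For Dgat2 it was -0.47 (SE 0.13), 72.0% of WT (adjusted p = 0.0345). After differentiation the differences were -1.39 (SE 0.11; 38.2% of WT) for Dgat1 and -1.67 (SE 0.13; 31.4% of WT) for Dgat2. Dgat1 rose by 2.46 in WT and 2.41 in D1D2KO cells, a difference in response of -0.05 (SE 0.15) that did not pass the test (limma, adjusted p = 0.964). Dgat2 rose by 4.27 in WT and 3.07 in D1D2KO cells, a difference of -1.20 (SE 0.18; adjusted p = 0.00271). In all 4 genotype comparisons every D1D2KO sample lay below every WT sample. The call of Dgat2 in undifferentiated cells ended without any 1 of the 6 undifferentiated samples (adjusted p from 0.0530 to 0.126) and after quantile normalization (adjusted p = 0.0501). Each gene was read by 1 probe set (10429926 for Dgat1 and 10565775 for Dgat2), whose place relative to the deleted sequence was not given in the sources used here, so the percentages are of signal and cannot be read as transcript left.

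**Figure D1:**
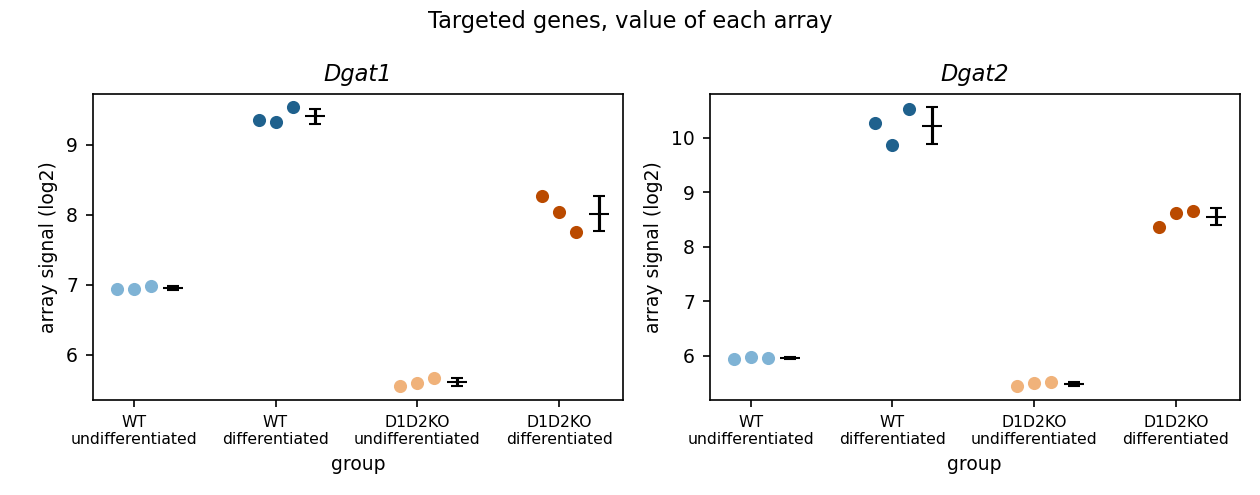
Signal (log2) of Dgat1 and Dgat2 on each array, with the mean and SD of each group of 3 samples beside the points. D1D2KO samples lay below WT samples in both states, and the group means of Dgat2 after differentiation were 10.22 in WT and 8.55 in D1D2KO cells.

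Differentiation of WT cells was examined next, as the reference for the mutant response, and the largest rises were those of adipocyte genes. Thrsp, a regulator of lipogenesis, rose by 6.05 (SE 0.21), which is 66.3-fold, and Adipoq, which encodes adiponectin, rose by 6.03 (SE 0.12), which is 65.3-fold (limma, adjusted p = 1.86e-15). Retn, which encodes resistin, rose by 5.77, the glycerol-3-phosphate dehydrogenase Gpd1 by 5.71, the fatty acid carrier Fabp4 by 5.24, the melanocortin receptor accessory protein Mrap by 5.21 and the amino acid transporter Slc36a2 by 5.06. Acute-phase genes were among them, with Lrg1 at 5.71, Hp (haptoglobin) at 5.49 and Orm1 (orosomucoid) at 5.20. Orm1 started at 3.79, under the lower quartile of every array, so the size of its rise is uncertain. The largest falls were those of the neuropeptide Y receptor Npy1r (-3.89, SE 0.10), the leptin receptor Lepr (-3.76, SE 0.09), the myeloid lectin Clec4n (-3.55) and the steroid dehydrogenase Akr1c14 (-2.83). The collagenase Mmp13 (-2.64), the proteoglycan Spock3 (-2.59), the urea transporter Slc14a1 (-2.55), the matrix protein Egfl6 (-2.49), the Notch ligand Dner (-2.47) and the endothelin receptor Ednrb (-2.40) fell as well. By the rule that picked them, none of these genes had overlapping values in the 3 differentiated and 3 undifferentiated samples. In all, 6794 of 19938 genes changed, 2934 up and 3860 down, and 519 rose and 397 fell by at least 2-fold.

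Of 27 tested gene lists, which were fixed before the data were examined, 17 were called in WT cells by camera with a preset correlation of 0.01, 12 up and 5 down, and 8 of the calls held with an estimated correlation. Among 26 adipocyte markers, 25 rose and 1 fell, and the counts adjusted over the list alone were the same (median 3.97, camera adjusted p = 3.53e-35). Of 18 genes of triacylglycerol synthesis 12 rose and 2 fell, or 12 and 3 adjusted over the list alone (median 0.68, adjusted p = 2.71e-07), led by Gpd1, the acyltransferase Agpat2 (4.28), Dgat2 (4.27) and the phosphatidate phosphatase Lpin1 (2.78), while Gpat4 (-0.21) and Lpin3 (0.03) did not pass. Of 19 lipid droplet proteins 13 rose and 1 fell, in both adjustments (median 0.91, adjusted p = 2.07e-09), with perilipin Plin1 at 4.58, Cidec at 4.56, the lipase inhibitor G0s2 at 4.10 and the lipase Pnpla2 at 3.78. Of 11 lipolysis genes 10 rose and 1 fell, also when adjusted over the list alone (median 3.49, adjusted p = 1.21e-14), among them the hormone-sensitive lipase Lipe (3.97). In fatty acid synthesis 15 of 20 rose and 2 fell in both adjustments (median 2.30, adjusted p = 4.69e-13), led after Thrsp by the pyruvate carboxylase Pcx (4.60), the elongase Elovl3 (3.80) and the acetyl-CoA synthetase Acss2 (3.78). That call was lost at an adjusted p = 0.0615 with an estimated correlation. The desaturases Fads1 (-0.16) and Fads2 (0.09) did not pass. In fatty acid uptake 9 of 15 rose and 5 fell in both adjustments (median 0.38, adjusted p = 0.000972, and adjusted p = 0.164 with an estimated correlation), and 3 fell without WT undifferentiated replicate 1 or 3 or WT differentiated replicate 1. The scavenger receptor Cd36 rose by 3.96 and the carrier Fabp5 by 2.54.

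Genes of fuel oxidation rose in WT cells, and those of fibroblasts and of dividing cells fell. Of 24 genes of fatty acid oxidation 23 rose and 1 fell (median 1.45, camera adjusted p = 1.34e-20), among them the peroxisomal Pex11a (3.42), the kinase Pdk4 (2.63), the uncoupling protein Ucp3 (2.27) and the dehydrogenase Acadm (2.01). All 22 genes of the tricarboxylic acid cycle and respiratory chain rose (median 1.01, adjusted p = 3.49e-18), with Idh3a at 1.62 and citrate synthase Cs at 1.51. Of 19 genes of glucose metabolism 18 rose (median 1.29, adjusted p = 4.79e-15, and adjusted p = 0.104 with an estimated correlation), including the insulin-responsive transporter Slc2a4 (2.21) and transketolase Tkt (1.77). Of 23 fibroblast and matrix genes 20 fell (median -0.42, adjusted p = 8.39e-08), among them lumican Lum (-1.33), Fap (-0.80) and the collagen Col1a2 (-0.72), while vimentin Vim (0.11) did not pass. For these 4 groups the counts adjusted over the list alone were the same. Of 23 cell cycle genes 19 fell, 20 adjusted over the list alone (median -0.47, adjusted p = 7.42e-08, and adjusted p = 0.153 with an estimated correlation), with topoisomerase Top2a at -0.81 and Mki67 at -0.77. Macrophage markers fell in 12 of 13 cases in both adjustments (median -0.98, adjusted p = 4.79e-10, and adjusted p = 0.0615 with an estimated correlation), led by lysozyme Lyz2 (-2.32) and Csf1r (-1.59).

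Smaller shifts in WT cells included inhibitors of adipogenesis and neural genes. Of 15 preadipocyte and Wnt genes 8 fell and 1 rose in both adjustments (median -0.27, camera adjusted p = 0.0194, and adjusted p = 0.302 with an estimated correlation), led by the ligand Wnt5a (-1.84). Of 11 neural markers 8 fell in both adjustments, 4 without WT undifferentiated replicate 1 (median -0.35, adjusted p = 0.000175), with the glial filament gene Gfap at -2.21. Brown adipocyte genes rose in 7 of 15 cases and fell in 1, or 2 adjusted over the list alone (median 0.19, adjusted p = 0.0161, and adjusted p = 0.267 with an estimated correlation). In that list the respiratory subunits Cox7a1 and Cox8b rose by 3.62 and 2.53 and the deiodinase Dio2 fell by 1.94. Cholesterol synthesis had 9 of 20 genes up and 1 down in both adjustments (median 0.25, adjusted p = 0.00669, and adjusted p = 0.466 with an estimated correlation), with Pmvk at 1.34. In the oxidative stress list 9 of 18 rose, among them catalase Cat (2.02), and 6 fell, or 3 without WT undifferentiated replicate 1, with the same counts adjusted over the list alone (median 0.16, adjusted p = 0.0293, and adjusted p = 0.222 with an estimated correlation). The lists not called were phospholipid synthesis (median -0.03), the unfolded protein response (-0.10), inflammatory and acute-phase genes (0.10), interferon-stimulated genes (0.25; adjusted p = 0.0808) and Hox genes (-0.08). Endothelial (-0.06), skeletal muscle (0.08), bone and cartilage (-0.05), epithelial (0.02) and liver and blood (0.13) markers were not called either.

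Differentiation of D1D2KO cells addressed whether cells deficient in both enzymes still took up the adipocyte programme. Adipoq rose by 7.41 (SE 0.12), from a low starting signal of 4.37, and Fabp4 by 6.70 (SE 0.12), which is 104-fold (limma, adjusted p = 1.16e-16 for Adipoq). Retn and Hp rose by 6.39, Gpd1 by 6.22, Thrsp by 5.70, the carbonic anhydrase Car3 by 5.69, the thyrotropin receptor Tshr by 5.49, the activin-type receptor Acvr1c by 5.42 and Orm1 by 5.34. Tshr, Acvr1c and Orm1 started at 3.81, 3.95 and 3.69, under the lower quartile of every array, so the sizes of their rises are uncertain. The largest falls were again those of Lepr (-4.18), Npy1r (-4.07), Clec4n (-3.88), Akr1c14 (-2.99) and Mmp13 (-2.98), followed by the secreted protein C1qtnf3 (-2.88), Egfl6 (-2.87), Slc14a1 (-2.86), the collagen Col14a1 (-2.76) and the neural fatty acid carrier Fabp7 (-2.68). By the rule that picked them, none of these genes had overlapping samples between the states. In all, 7311 genes changed, 3075 up and 4236 down, with 710 rises and 584 falls of at least 2-fold. Between the genotypes, 2199 genes rose in both and 3289 fell in both, where independent lists would share 453 and 820, and 11 moved in opposite directions. Across genes, which are not independent replicates, the 2 responses had a Pearson correlation of 0.934 and a Spearman correlation of 0.816.

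Of the 27 tested lists 18 were called in D1D2KO cells, 11 up and 7 down, and 8 held with an estimated correlation. The adipocyte markers again had 25 rises and 1 fall among 26 in both adjustments (median 4.15, camera adjusted p = 3.03e-33). Lipid droplet proteins had 12 rises and 1 fall among 19 (median 1.17, adjusted p = 1.50e-09), with Plin1 at 5.11, Cidec at 5.02 and G0s2 at 4.67. Triacylglycerol synthesis had 12 rises and 2 falls among 18 (median 1.03, adjusted p = 9.76e-09), with the acyltransferases Agpat2 at 4.65 and Gpat3 at 4.16 and the gluconeogenic enzyme Pck1 at 3.86. Lipolysis had 10 rises and 1 fall among 11 (median 3.80, adjusted p = 4.03e-14), fatty acid oxidation 23 and 1 among 24 (median 1.95, adjusted p = 2.97e-22), and the tricarboxylic acid cycle and respiratory chain 22 rises among 22 (median 1.45, adjusted p = 1.49e-21). Matrix genes fell in 21 of 23 cases, and 1 more rose when adjusted over the list alone (median -0.89, adjusted p = 8.37e-13). The connective tissue growth factor Ccn2 fell by 1.72 and tenascin Tnc by 1.68. Neural markers fell in 8 of 11 cases (median -0.50, adjusted p = 0.000208). These are the 8 lists that held with an estimated correlation, and for those without another count given here the counts adjusted over the list alone were the same.

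The other 10 called lists did not hold with an estimated correlation. Fatty acid synthesis had 15 rises and 5 falls among 20 (median 2.09, camera adjusted p = 9.53e-08, and adjusted p = 0.156 with an estimated correlation), with the desaturase Scd1 at 3.54. Glucose metabolism had 18 rises among 19 (median 1.69, adjusted p = 2.81e-17, and adjusted p = 0.0863 with an estimated correlation), with glycogen synthase Gys1 and Slc2a4 at 2.75. Cell cycle genes fell in 20 of 23 cases, 22 adjusted over the list alone (median -0.48, adjusted p = 3.18e-07, and adjusted p = 0.156 with an estimated correlation), and macrophage markers in 12 of 13 (median -1.08, adjusted p = 1.70e-09, and adjusted p = 0.0728 with an estimated correlation). Of 16 interferon-stimulated genes 8 fell and 0 rose in both adjustments (median -0.34, adjusted p = 0.00327, and adjusted p = 0.382 with an estimated correlation), led by Ifit2 (-1.03), Ifit3 (-0.99) and Ifit1 (-0.87). Fatty acid uptake was called up (9 rises and 3 falls of 15, 10 and 3 adjusted over the list alone; median 0.78, adjusted p = 0.137 with an estimated correlation). Brown adipocyte genes (8 rises and 2 falls of 15 in both adjustments; median 0.29, adjusted p = 0.156 with an estimated correlation) and oxidative stress genes (8 and 5 of 18, 9 and 6 adjusted over the list alone; median 0.16, adjusted p = 0.247 with an estimated correlation) were called up as well. Preadipocyte and Wnt genes (1 rise and 8 falls of 15 in both adjustments; median -0.27, adjusted p = 0.246 with an estimated correlation) were called down. Hox genes were also called down (1 rise and 8 falls of 24 in both adjustments; median -0.15, adjusted p = 0.433 with an estimated correlation), led by Hoxb9 (-0.83). Their 8 falls became 5 and 4 without D1D2KO undifferentiated replicates 2 and 3, and 5 without D1D2KO differentiated replicate 2.

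**Figure D2:**
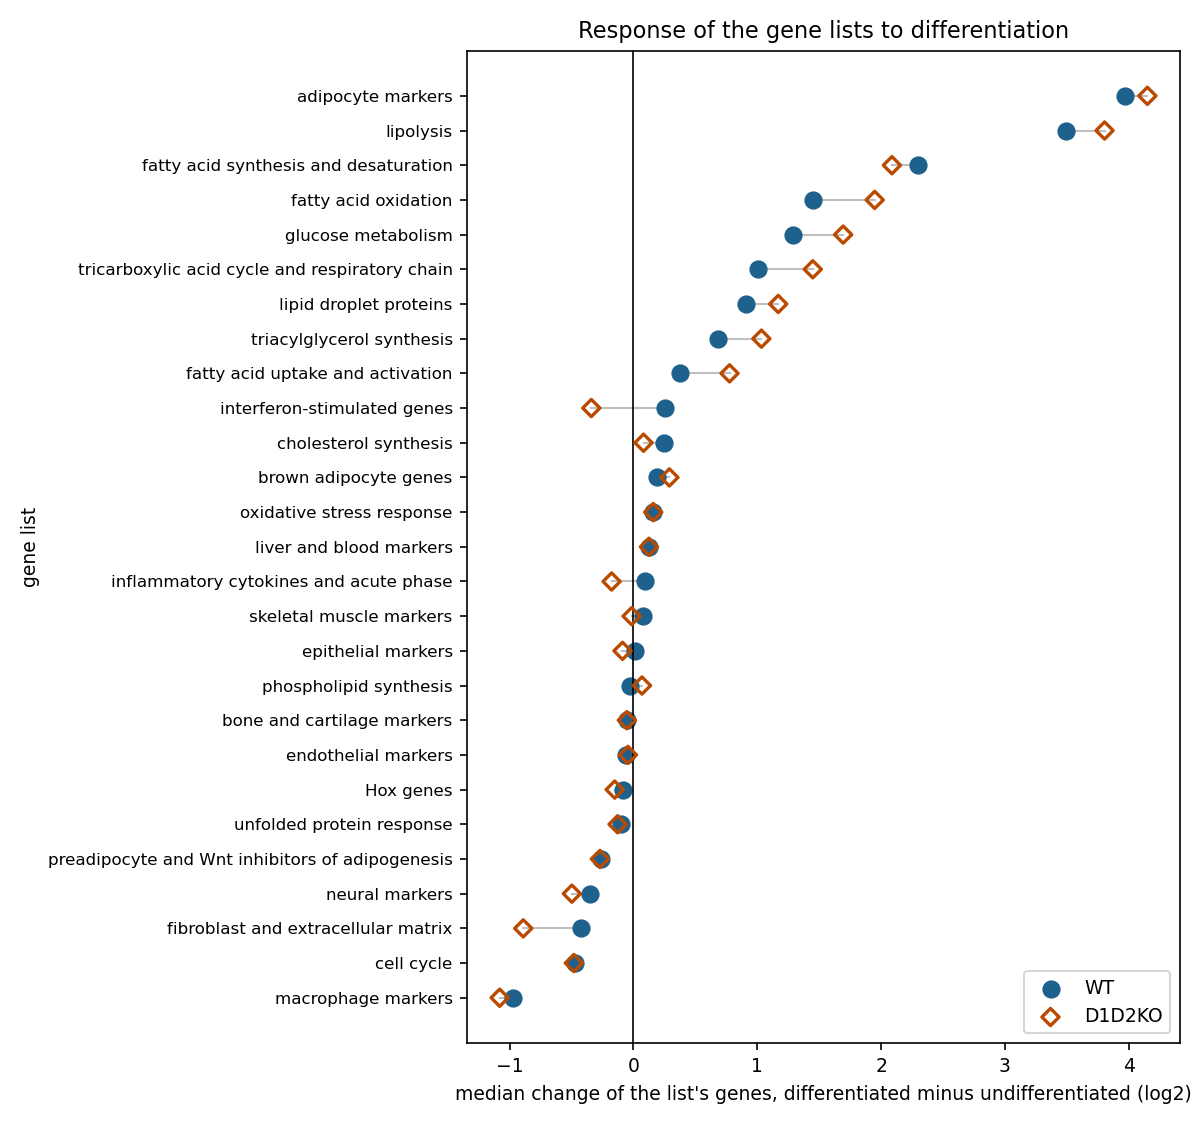
Median change (log2, differentiated minus undifferentiated) of the measured genes of 27 lists, with WT as filled circles and D1D2KO as open diamonds joined by a line. The adipocyte markers had medians of 3.97 and 4.15, and the interferon-stimulated genes 0.25 and -0.34.

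The test of the difference between the 2 responses asked which genes answered the adipogenic treatment differently in D1D2KO cells. The prolyl hydroxylase Egln3 (difference 1.82, SE 0.17; limma, adjusted p = 0.000103) and the mitophagy receptor Bnip3 (1.54, SE 0.17) rose more in D1D2KO cells. The transglutaminase subunit F13a1 (1.77), the acyltransferase Gpat3 (1.52), Itih5 (1.46), the calmodulin regulator Pcp4 (1.45), Fabp4 (1.45), Brinp3 (1.41), the relaxin-family receptor Rxfp2 (1.39) and Adipoq (1.38) also had a more positive response there. The peptidase Folh1 (-2.55, SE 0.25), the antimicrobial lectin Reg3g (-1.47), Tnc (-1.22), Dgat2 (-1.20), the prostaglandin synthase Ptgs2 (-1.20), the matrix protein Efemp1 (-1.11), the growth factor Pgf (-1.10), the serotonin receptor Htr1b (-1.08) and the guanylate-binding protein Gbp3 (-1.05) had a more negative response. The antiviral gene Mx2 (-1.08; adjusted p = 0.0421) was called too, but not without any 1 of the samples other than WT differentiated replicate 3 and D1D2KO differentiated replicate 2 (adjusted p from 0.0541 to 0.124) nor with the replicate number as a block (adjusted p = 0.0628) or array weights (-0.72, adjusted p = 0.155). Adipoq and Acvr1c in undifferentiated D1D2KO cells, Brinp3 and Rxfp2 in differentiated cells and Mx2 in all groups had group means near the lower quartile of the arrays. Egln3, Bnip3, F13a1, Itih5, Fabp4, Brinp3 and Rxfp2 were lower in undifferentiated D1D2KO cells and did not pass between the genotypes after differentiation. F13a1, for example, started at 8.47 against 10.06 and ended at 10.21 against 10.03. In all, 291 genes passed, 149 with a more positive and 142 with a more negative response. That count fell to 159 and 176 without WT undifferentiated replicates 1 and 2, to 168, 187 and 171 without D1D2KO undifferentiated replicates 1, 2 and 3, and to 185 and 190 without D1D2KO differentiated replicates 1 and 2. It was 449 without WT differentiated replicate 3.

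Of the 27 lists 14 were called for a different response, 9 up and 5 down. The calls of the adipocyte, respiratory and matrix lists held with an estimated correlation. Adipocyte markers responded more strongly in D1D2KO cells, with 22 of 26 differences above 0 (median 0.47, camera adjusted p = 6.49e-14), and 7 passed on their own, 10 adjusted over the list alone and 4 without WT undifferentiated replicate 1. Pck1 (1.30) and Acvr1c (0.94) were among them after Fabp4 and Adipoq. In the tricarboxylic acid cycle and respiratory chain 4 of 22 genes passed and 19 adjusted over the list alone (median 0.41, adjusted p = 2.14e-19), with Idh3a at 0.85 and the cytochrome Cyc1 at 0.66. That 4 became 7 without D1D2KO differentiated replicate 3. It became 2 without any 1 of WT undifferentiated replicates 1 and 2, WT differentiated replicate 2, the 3 D1D2KO undifferentiated samples and D1D2KO differentiated replicates 1 and 2. Matrix genes responded more negatively, 6 of 23 on their own and 15 adjusted over the list alone (median -0.36, adjusted p = 3.07e-16), with Ccn2 at -1.04, Ccn1 at -0.79 and the actin-binding Tagln at -0.77. Tagln is also a smooth muscle marker. The 10 smooth muscle markers not looked at before had a median of -0.31 (camera, adjusted p = 0.000122, and adjusted p = 0.0845 with an estimated correlation). Of these named genes every call held without any 1 sample.

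Fatty acid oxidation had 5 of 24 genes with a more positive response, 17 adjusted over the list alone (median 0.46, camera adjusted p = 1.74e-14, and adjusted p = 0.102 with an estimated correlation), including Etfdh (0.68) and Acadm (0.66). Without 1 sample its 5 became 3 (WT undifferentiated replicate 3), 9 (WT differentiated replicate 3), 11 (D1D2KO differentiated replicate 3) or 2 (any of the remaining 9), and with the replicate number as a block 3. Glucose metabolism had 6 of 19, 10 adjusted over the list alone (median 0.53, adjusted p = 1.03e-11, and adjusted p = 0.173 with an estimated correlation), with Gys1 at 0.98. Between the genotypes this list had a median of -0.44 in undifferentiated and 0.05 in differentiated cells. The larger response of the list thus came with a lower start in D1D2KO cells and a similar end. Its 6 became 10 without D1D2KO differentiated replicate 3 and 3 without WT differentiated replicate 1, D1D2KO undifferentiated replicate 1 or D1D2KO differentiated replicate 2. It became 2 without WT undifferentiated replicate 1 or 2, WT differentiated replicate 2, D1D2KO undifferentiated replicate 3 or D1D2KO differentiated replicate 1. Interferon-stimulated genes responded more negatively, 5 of 16 and 13 adjusted over the list alone (median -0.68, adjusted p = 6.79e-17, and adjusted p = 0.0624 with an estimated correlation), with Gbp3 (-1.05) and the RNA sensor Ifih1 (-0.71). Their 5 became 12 without WT differentiated replicate 3 and 3 without WT undifferentiated replicate 3. It stayed within 1.5 times without D1D2KO undifferentiated replicate 1 or D1D2KO differentiated replicate 2, and was 2 without any of the other 8 samples. With the replicate number as a block it was 2, and with number and genotype together 3.

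Smaller lists moved in both directions. Lipolysis (2 of 11, or 7 up and 1 down adjusted over the list alone; median 0.48, adjusted p = 0.141 with an estimated correlation) included the lipase Mgll (0.88) and the phosphodiesterase Pde3b (0.83), both with a more positive response. Fatty acid synthesis (0 up and 2 down of 20, 6 down adjusted over the list alone; median -0.21, adjusted p = 0.234 with an estimated correlation) included the elongase Elovl6 (-0.98) and the desaturase Fads2 (-0.82). Inflammatory genes (1 up and 2 down of 22, 1 and 6 adjusted over the list alone; median -0.33, adjusted p = 0.174 with an estimated correlation) included Ptgs2 (-1.20). Triacylglycerol synthesis (2 up and 1 down of 18, 3 and 1 adjusted over the list alone; median 0.19, adjusted p = 0.102 with an estimated correlation) and brown adipocyte genes (1 up of 15, 4 adjusted over the list alone; median 0.13, adjusted p = 0.154 with an estimated correlation) were called up. In the brown list the changed gene was Cox8b (0.98). Lipid droplet proteins (0 of 19, 4 up adjusted over the list alone; median 0.13, adjusted p = 0.173 with an estimated correlation) and fatty acid uptake (1 up of 15 in both adjustments; median 0.18, adjusted p = 0.194 with an estimated correlation) were called up too. Epithelial markers were called down (0 up and 1 down of 10 in both adjustments; median -0.14, adjusted p = 0.154 with an estimated correlation).

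In undifferentiated cells the genotypes were compared before any treatment. Of the largest differences, 4 cardiac genes were higher in D1D2KO cells and 3 Y-linked genes were near the floor. Among the genes higher in D1D2KO cells were the cardiac myosin Myh6 (1.26, SE 0.09), the cardiac actin Actc1 (1.22, SE 0.14), phospholamban Pln (1.18, SE 0.17) and the natriuretic peptide Nppa (0.90). The olfactory receptor Olfr767 (1.24), Gdpd3 (0.88), the lipid transfer protein Stard10 (0.81), the neuropeptide Adcyap1 (0.79) and the keratan proteoglycan Kera (0.76) were higher as well, with 1 predicted gene. The Y-linked genes Eif2s3y (-4.99, SE 0.09), Uty (-4.05) and Kdm5d (-2.36) were lower in all 3 D1D2KO samples, and Xist, the X-inactivation transcript, was higher (0.56, SE 0.07; limma, adjusted p = 0.000187). The mean of these 3 Y-linked genes over both states stood at percentile 7.42 of all genes in D1D2KO and 63.1 in WT cells. The tripartite-motif genes Trim12a (-3.72) and Trim30d (-3.22), Pcp4 (-2.51), the smooth muscle myosin Myh11 (-2.39, SE 0.09), the BMP antagonist Grem1 (-2.38), the muscarinic receptor Chrm2 (-2.17) and neuronatin Nnat (-1.91) were lower. The D1D2KO means of Trim12a (3.67), Trim30d (2.45), Eif2s3y (2.65), Uty (2.89) and Kdm5d (3.64) lay under the lower quartile of every array. They did so after differentiation too (3.60, 2.86, 2.95, 3.12 and 3.63), so the sizes of these differences are uncertain. Apart from Xist, the genes named here were picked among those without overlapping samples, and Xist had no overlap either. Olfr767 was not called without WT undifferentiated replicate 1 or 2 or D1D2KO undifferentiated replicate 3 (adjusted p of 0.0806, 0.114 and 0.0998) or with trended and robust eBayes (adjusted p = 0.0727).

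In all, 1600 genes differed, 878 higher and 722 lower in D1D2KO cells, and only 4 higher and 54 lower by at least 2-fold. The balance depended on the scaling, with 54.9% higher as deposited, 32.3% (431 of 1334) after centring each array on its median and 44.0% (369 of 838) after quantile normalization. The count was 571 and 339 without WT replicates 1 and 2, and 588, 1031 and 392 without D1D2KO replicates 1, 2 and 3 of the undifferentiated cells. Beside the genes above, Fabp4 (-1.20), Adipoq (-0.97), Car3 (-0.68), the desaturase Scd1 (-0.66), Mgll (-0.66), Ptgs2 (-0.97) and Hp (-0.85) were lower in D1D2KO cells. Camera called 11 lists, 1 up and 10 down, none of which held with an estimated correlation (lowest adjusted p = 0.270). Glucose metabolism was lowest, with 11 of 19 genes lower, 12 adjusted over the list alone (median -0.44, adjusted p = 1.15e-11, and adjusted p = 0.381 with an estimated correlation). It included the phosphofructokinases Pfkp (-1.03) and Pfkl (-0.89), the kinase Pdk1 (-0.75) and Tpi1 (-0.68), and 6 were lower without WT undifferentiated replicate 2 or D1D2KO undifferentiated replicate 3. Cell cycle genes were lower in 9 of 23 cases, 16 adjusted over the list alone (median -0.29, adjusted p = 3.68e-11, and adjusted p = 0.270 with an estimated correlation), with Top2a at -0.48. That 9 became 5 and 1 without WT undifferentiated replicates 1 and 2, 4 and 1 without D1D2KO undifferentiated replicates 1 and 3, and 4 after quantile normalization. Skeletal muscle genes were called up (2 higher and 1 lower of 16, 6 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.270 with an estimated correlation), with Actc1 higher and desmin Des (-1.48) lower.

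The other lists called in undifferentiated cells had few members that passed. Adipocyte markers had 1 higher and 4 lower of 26, or 3 and 4 adjusted over the list alone (median -0.04, camera adjusted p = 0.0351, and adjusted p = 0.529 with an estimated correlation). Oxidative stress genes had 2 lower of 18 in both adjustments (median -0.16, adjusted p = 0.270 with an estimated correlation), the metallothionein Mt2 (-0.63) and the glutathione transferase Gstm1 (-0.45). Triacylglycerol synthesis had 2 lower of 18, the targeted Dgat1 and Dgat2, or 1 higher and 3 lower adjusted over the list alone (median -0.10, adjusted p = 0.381 with an estimated correlation). Cholesterol synthesis (1 lower of 20; median -0.18, adjusted p = 0.528 with an estimated correlation) and fatty acid uptake (1 lower of 15; median -0.17, adjusted p = 0.525 with an estimated correlation) were called down, with the same counts adjusted over the list alone. So were the tricarboxylic acid cycle and respiratory chain (0 of 22; median -0.12, adjusted p = 0.525 with an estimated correlation) and fatty acid oxidation (0 of 24; median -0.14, adjusted p = 0.682 with an estimated correlation), with 0 calls in both adjustments. Fatty acid synthesis was called down with 1 higher and 2 lower of 20, or 1 and 3 adjusted over the list alone (median -0.10, adjusted p = 0.729 with an estimated correlation). Interferon-stimulated genes (0 of 16; median -0.01) and the unfolded protein response (0 of 22; median -0.04) were not called.

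In differentiated cells the genotypes were compared to see how adipocytes deficient in both enzymes differed from WT adipocytes. Of 23 matrix genes 14 were lower in D1D2KO cells, and so were 14 of 16 interferon-stimulated genes, while 14 of 24 genes of fatty acid oxidation were higher. Pck1 (1.74, SE 0.15; 3.34-fold), Cox8b (1.28, SE 0.12), leptin Lep (1.09, SE 0.12), Gpat3 (1.07), the carboxylesterase Ces1d (0.95) and the growth factor receptor Met (0.93) were higher, with Pln (1.91), Actc1 (1.20), Tmem182 (1.15) and Myh6 (0.94). Besides the Y-linked Eif2s3y (-5.07) and Uty (-3.67), Trim12a (-3.52), Trim30d (-3.18), Myh11 (-2.50, SE 0.09), calponin Cnn1 (-2.43, SE 0.12), Folh1 (-2.42), Des (-2.40), the smooth muscle actin Actg2 (-2.38) and Ptgs2 (-2.17, SE 0.14; limma, adjusted p = 4.24e-08) were lowest. These genes too were picked among those without overlapping samples. In all, 2726 genes differed, 1246 higher and 1480 lower, and 7 higher and 74 lower by at least 2-fold, and the count was 1344 without WT differentiated replicate 2. The share of higher genes was 45.7% as deposited, 29.5% (773 of 2618) after centring and 47.2% (981 of 2080) after quantile normalization. Genotype differences in the 2 states shared 232 higher and 353 lower genes, where 54.9 and 53.6 would be shared by independent lists, with 24 in opposite directions and a Pearson correlation of 0.604 across genes.

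Camera called 14 lists between the genotypes in differentiated cells, 6 up and 8 down, and only the matrix list held with an estimated correlation. Of 23 matrix genes 14 were lower, 18 adjusted over the list alone (median -0.30, camera adjusted p = 9.85e-15, and 0.00598 with an estimated correlation), including Ccn2 (-1.38), Tnc (-1.37), Tagln (-1.29) and Ccn1 (-0.91). Tagln is also a smooth muscle marker, and of 10 smooth muscle markers listed afterwards and not looked at before 8 were lower too (median -0.66, adjusted p = 0.00523 with an estimated correlation). Of 16 interferon-stimulated genes 14 were lower in both adjustments (median -0.71, adjusted p = 4.89e-14, and adjusted p = 0.198 with an estimated correlation), including Ifit1 (-1.31), Ifit3 (-0.96), Mx2 (-0.93) and Gbp3 (-0.93). Inflammatory genes were lower in 10 of 22 cases, or 11 lower and 1 higher adjusted over the list alone (median -0.24, adjusted p = 1.06e-05, and adjusted p = 0.249 with an estimated correlation), among them Ptgs2, the cytokine Il6 (-1.08, at low group means of 3.62 and 2.53) and Saa3 (-1.05). Fatty acid synthesis had 8 of 20 genes lower in both adjustments (median -0.35, adjusted p = 2.74e-07, and adjusted p = 0.249 with an estimated correlation), with Elovl6 (-1.32), the ATP citrate lyase Acly (-1.26), Fads2 (-0.88) and the desaturase Scd2 (-0.72), and 13 lower without WT differentiated replicate 2. Cholesterol synthesis had 9 of 20 lower, 12 adjusted over the list alone (median -0.31, adjusted p = 1.65e-06, and adjusted p = 0.249 with an estimated correlation), among them Idi1 (-0.61) and Fdps (-0.48). Cell cycle genes were lower in 13 of 23 cases, 20 adjusted over the list alone (median -0.32, adjusted p = 1.02e-10, and adjusted p = 0.249 with an estimated correlation), 6 without WT differentiated replicate 2 and 8 after quantile normalization, with Tpx2 at -0.46. Beside these groups the Y-linked Kdm5d (-1.92) was lower and Xist higher (0.47, SE 0.07; adjusted p = 0.000541).

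Of 26 adipocyte markers 11 were higher and 1 lower, or 13 and 2 adjusted over the list alone (median 0.25, camera adjusted p = 0.000100, and adjusted p = 0.249 with an estimated correlation), with Pck1, Lep and Acvr1c (0.66) higher and Nnat (-1.18) lower. The 11 became 7 and 4 without WT differentiated replicates 1 and 2, and 6 and 5 without D1D2KO differentiated replicates 1 and 2. Fatty acid oxidation had 14 of 24 genes higher, 15 adjusted over the list alone (median 0.35, adjusted p = 6.12e-06, and adjusted p = 0.249 with an estimated correlation), including the coactivator Ppargc1a (0.62), the receptor Ppara (0.53) and Hadhb (0.47). The tricarboxylic acid cycle and respiratory chain had 11 of 22 higher, 16 adjusted over the list alone (median 0.29, adjusted p = 1.26e-07, and adjusted p = 0.249 with an estimated correlation), including Idh3a (0.62) and Cyc1 (0.49). That 11 became 7 and 3 without WT differentiated replicates 1 and 2, 4 without D1D2KO differentiated replicate 1 or 2, and 6 after centring. Lipolysis had 6 of 11 higher, or 7 higher and 1 lower adjusted over the list alone (median 0.31, adjusted p = 0.249 with an estimated correlation), with Ces1d and Pde3b (0.52), and 2 without WT differentiated replicate 2 or D1D2KO differentiated replicate 1. Lipid droplet proteins had 6 of 19 higher, 9 adjusted over the list alone (median 0.26, adjusted p = 0.249 with an estimated correlation), but 0 without WT differentiated replicate 2 or D1D2KO differentiated replicate 1 and 3 without D1D2KO differentiated replicate 2. Brown adipocyte genes had 5 higher and 1 lower of 15, or 6 and 1 adjusted over the list alone (median 0.24, adjusted p = 0.249 with an estimated correlation), with Cox8b. Those 5 became 2 without WT differentiated replicate 2 and 3 without any D1D2KO differentiated sample or after centring. Oxidative stress genes were called down (0 higher and 4 lower of 18, or 1 and 6 adjusted over the list alone; median -0.13, adjusted p = 0.249 with an estimated correlation; 2 lower without WT differentiated replicate 2), with the peroxidase Gpx1 at -0.53. Hox genes were called down (0 higher and 2 lower of 24 in both adjustments; median -0.12, adjusted p = 0.459 with an estimated correlation), with Hoxd10 at -0.78 and Hoxc8 at -0.53. Triacylglycerol synthesis was not called (3 higher and 2 lower of 18, in both adjustments; median 0.09, adjusted p = 0.268), with Pck1 and Gpat3 higher and Dgat1 and Dgat2 lower. Glucose metabolism was not called either, with 1 higher and 0 lower of 19, or 0 and 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.577).

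**Figure D3:**
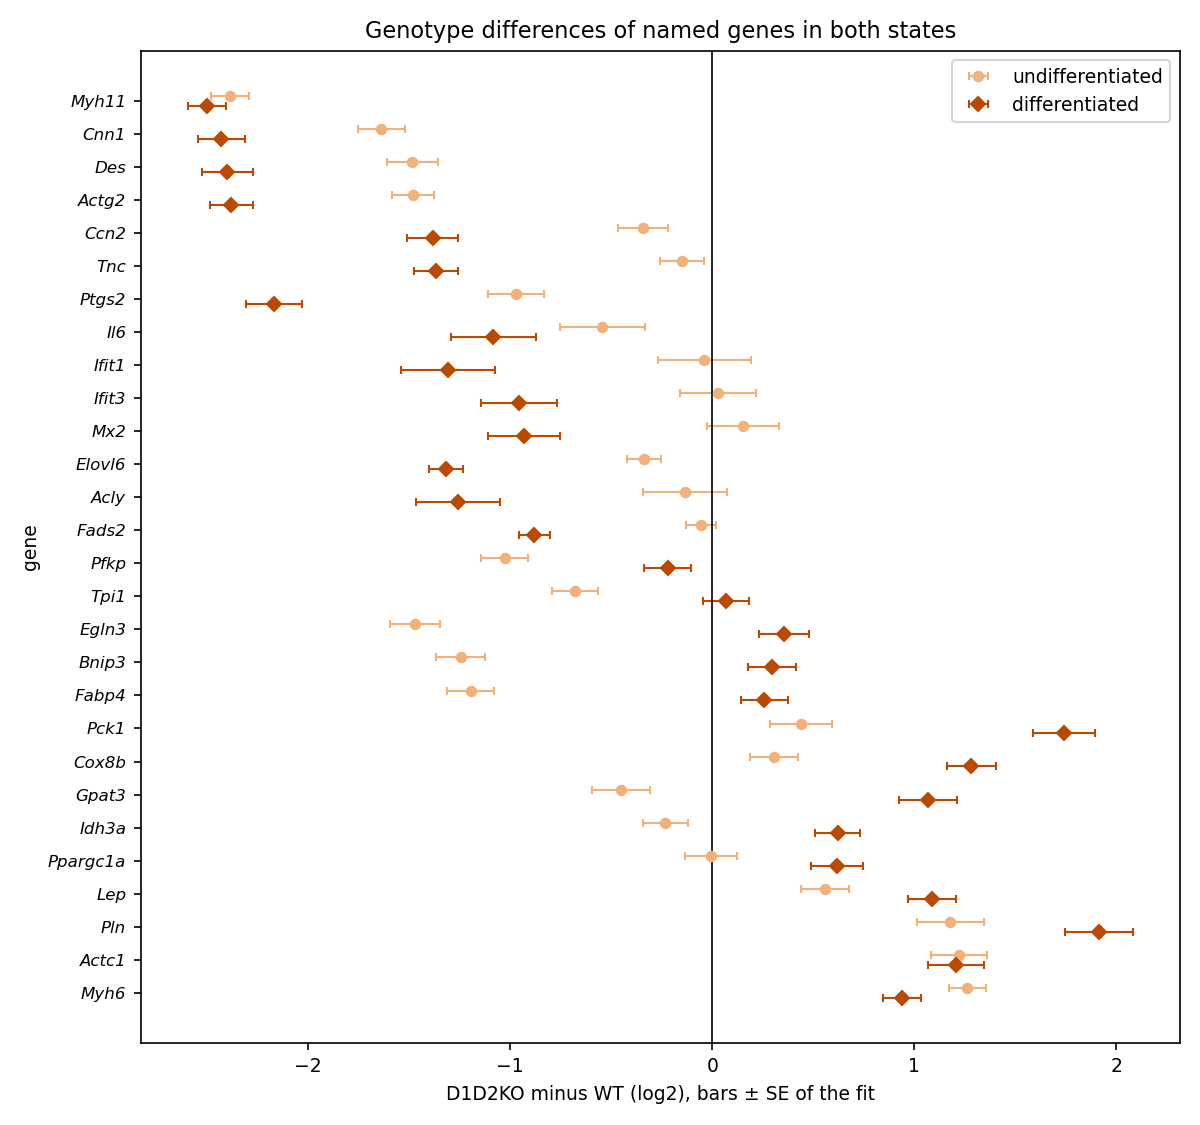
Difference between D1D2KO and WT cells (log2) for named genes in undifferentiated (circles) and differentiated (diamonds) cells, with bars for the SE of the fit and 3 samples per group. Pln stood at 1.18 and 1.91, Myh11 at -2.39 and -2.50, and Egln3 at -1.47 and 0.35.

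**Figure D4:**
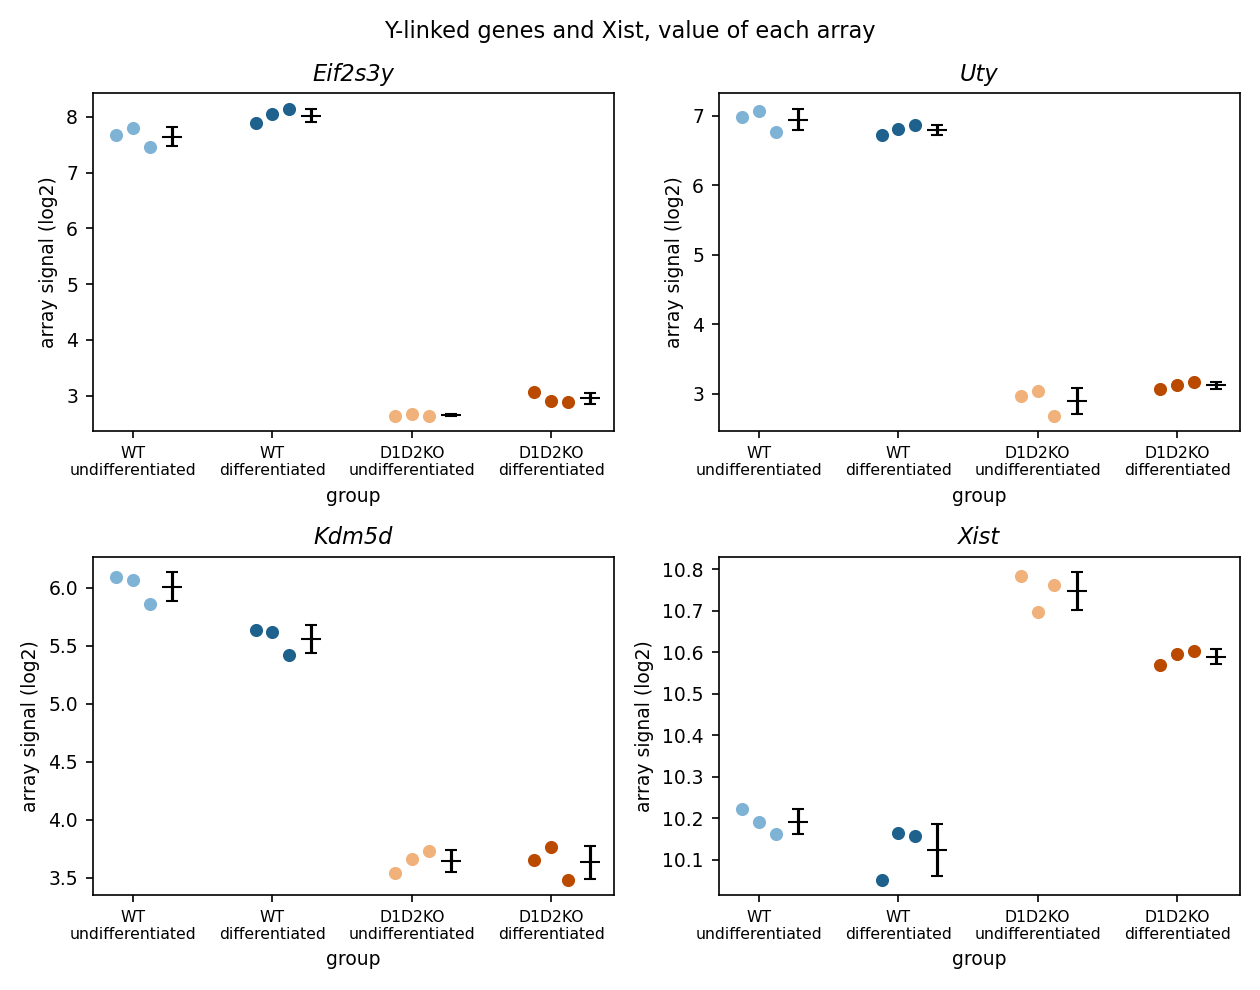
Signal (log2) of the Y-linked genes Eif2s3y, Uty and Kdm5d and of Xist on each array, with the mean and SD of each group of 3 samples. The vertical axes start above 0. Eif2s3y had group means of 7.64 and 8.02 in WT and 2.65 and 2.95 in D1D2KO cells.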

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

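The tests of Xist and of a lower share of the main cell type were chosen after the result was seen, and the bound for the Dgat1 neighbours was narrowed after its value was seen. The splits for the different response were set aside as undecided after their count was seen. The other tests, of X linkage, of the Dgat2 neighbours, of the mix of cell types and of other splits, were written before their result was known. The smooth and cardiac muscle lists were themselves written after the genotype differences had been seen.

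The results here were flagged because the response to differentiation differed between the genotypes in a test of the difference itself, which 291 genes and 14 lists passed. A more positive response in D1D2KO cells was seen for Egln3 (1.82), F13a1 (1.77), Bnip3 (1.54), Gpat3 (1.52), Itih5 (1.46), Pcp4 (1.45), Fabp4 (1.45), Brinp3 (1.41), Rxfp2 (1.39), Adipoq (1.38), Pck1 (1.30), Gys1 (0.98), Cox8b (0.98), Acvr1c (0.94), Mgll (0.88), Idh3a (0.85), Pde3b (0.83), Etfdh (0.68), Cyc1 (0.66) and Acadm (0.66). A more negative response was seen for Folh1 (-2.55), Reg3g (-1.47), Tnc (-1.22), Dgat2 (-1.20), Ptgs2 (-1.20), Efemp1 (-1.11), Pgf (-1.10), Htr1b (-1.08), Gbp3 (-1.05), Ccn2 (-1.04), Elovl6 (-0.98), Fads2 (-0.82), Ccn1 (-0.79), Tagln (-0.77) and Ifih1 (-0.71). Mx2 (-1.08) belonged to them too, but its call ended without any 1 of 10 samples, as given in the report. Of the lists, the median difference was 0.53 for glucose metabolism, 0.48 for lipolysis, 0.47 for adipocyte markers, 0.46 for fatty acid oxidation, 0.41 for the tricarboxylic acid cycle and respiratory chain, 0.19 for triacylglycerol synthesis, 0.18 for fatty acid uptake, 0.13 for brown adipocyte genes and 0.13 for lipid droplet proteins. It was -0.14 for epithelial markers, -0.21 for fatty acid synthesis, -0.33 for inflammatory genes, -0.36 for matrix genes and -0.68 for interferon-stimulated genes. The glucose list started lower in D1D2KO cells (median -0.44) and ended near WT (median 0.05). Of these lists only the adipocyte, tricarboxylic acid cycle and matrix calls held with an estimated correlation. Of 100 splits of the samples, drawn with a fixed seed, 3 gave as many genes as the 291, with 1247 and 355 in the highest others. The splits move the genotype differences into the spread or into the contrast, so their number decides nothing about chance. The split with 1247 exchanged the genotypes of all 6 differentiated samples and of 2 of the undifferentiated ones, while 2 other splits that exchanged as many gave 166 and 160, and the split with 355 exchanged 4 differentiated samples. Exchanging all 6 differentiated samples turns the contrast largely into a sum of the genotype differences of the 2 states, so many calls there can come from the genotype differences themselves. Why such splits gave unlike counts was not tested. For the 14 lists 13 of 100 splits gave as many, with 19 in the highest other, which decides nothing about chance for the same reason. Outside the named genes, 293 probe sets with no gene listed differed between the genotypes in differentiated cells.

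The comparisons of 2 groups had 3 samples against 3, whose 10 splits cannot give a share under 0.05. For genes, the real split was the only 1 of 10 with as many in each comparison, with 6794 and 7311 genes in the differentiation of WT and D1D2KO cells and 1600 and 2726 between the genotypes in undifferentiated and differentiated cells, and the highest other split gave 0. In D1D2KO differentiation, where the replicate numbers pair the samples, 3 of the 9 other splits part all 3 pairs as the real one does and 6 part 1 pair, and all gave 0 genes. In each comparison the other splits put samples of both real groups on each side, which moves the real differences into the spread. Counts of 0 genes were therefore likely in advance, with or without pairing, and decide nothing about chance. For lists, 4 of 10 splits gave as many as the real 17 in WT differentiation (highest other 18), 3 as many as 18 in D1D2KO differentiation (highest other 19), 1 as many as 11 in undifferentiated cells (highest other 5) and 2 as many as 14 in differentiated cells (highest other 20).

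The Y-linked genes Eif2s3y, Uty and Kdm5d were near the floor in all D1D2KO samples, and Xist was higher in D1D2KO cells by 0.557 in undifferentiated and 0.465 in differentiated cells. Loss of the Y chromosome from male cells would leave Xist unchanged. Both values lay more than 2 standard errors above 0, so that loss alone does not account for Xist. Xist already stood at 10.05 to 10.22 on the WT arrays, against 10.57 to 10.78 in D1D2KO, so the WT cultures need not have been male alone. Every WT array also carried Y-linked signal (Eif2s3y from 7.46 to 8.13), so neither mark was absent from any WT sample. Separate embryos could differ in sex, so the samples of a genotype may share 1 pool, which was not tested. A shift in the share of female cells could raise Xist whether or not male cells lost the Y chromosome, so such loss was not excluded. A different sex makeup of the embryos behind the genotypes needs both signs and may account for these 4 genes. The wider genotype differences were not concentrated on the X chromosome, since 11.5% of X-linked genes (85 of 739) were called in differentiated cells, against 13.8% of autosomal genes (2629 of 19106). With 2726 genes called, the 739 X-linked genes could not have made up most of them whatever their share. The percentages show only that X-linked genes were not called more often, and they do not exclude sex as a cause. Of 4 X-linked genes that escape inactivation 0 passed in either state, and effects of sex on autosomal genes stay open and were not tested.

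Genes near Dgat2 differed between the genotypes more often than genes elsewhere, and among its 100 nearest measured neighbours 10 were called in both states in 1 direction, among them Myo7a and Stard10, where the median window had 3 and 0.616% of 17206 windows had as many. DNA of another mouse strain carried along with the targeted allele may account for them, and an effect of the lost enzymes on these genes was not tested. Around Dgat1 the count was 2, which 77.2% of windows reach, so such DNA there cannot be told apart from no such DNA. Windows centred on adjacent genes share most of their members, so neither percentage counts independent regions or stands for a p-value. The bound written for Dgat1 asked only for a count at or under the median, which allowed for no spread. Trim12a and Trim30d, 162 and 165 measured genes from Dgat2 on the same chromosome, lay outside the window. The count therefore says nothing on whether such DNA reaches them.

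Among the genes with the largest differences, smooth muscle genes were lower and cardiac muscle genes higher in D1D2KO cells. A lower share of the main cell type would raise both only if that type expressed neither set. The smooth muscle genes Myh11 and Actg2 had high means in undifferentiated WT cells (10.60 and 10.67), so that was not established. The 22 smooth muscle markers had medians of -0.814 and -1.04 in undifferentiated and differentiated cells, and the 21 cardiac markers 0.39 and 0.21. These lists include genes that prompted them, and a lower share of a main type that expresses smooth muscle genes was not excluded. A different mix of cell types in the starting cultures was tested on members not looked at before, of which the smooth muscle members had medians of -0.428 and -0.66 in undifferentiated and differentiated cells (camera, adjusted p = 1.39e-07 and adjusted p = 1.10e-11). The cardiac members had medians of 0.28 and 0.16 (adjusted p = 0.0586 and adjusted p = 0.0302, the latter 0.179 with an estimated correlation), so the bound was not met in full and the mix cannot be told apart from an effect of the genotype on these genes. How the cultures of each genotype were prepared was not given, which keeps it open, and the effect of the genotype itself may also account for the pattern.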

How the results depend on the processing

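Leaving out WT undifferentiated replicate 3 or D1D2KO differentiated replicate 3 for list counts was chosen after seeing the data, and the other alternatives were set beforehand. No called result changed direction. The Dgat1 difference in response, which was not called, ran from -0.17 to 0.09 without 1 sample, and the share of higher genes in undifferentiated cells turned from 54.9% to 32.3% after centring. The counts of differentiation genes stayed within 1.5 times under all but the 2-fold minimum. At least 2-fold changes left 916 and 1294 genes in WT and D1D2KO differentiation, 58 and 81 between the genotypes in undifferentiated and differentiated cells and 39 with a different response. Between undifferentiated genotypes (1600 genes) quantile normalization gave 838, genes above the median signal 881, probe set level 635, only the 2 groups 2597 and array weights 4224. Between differentiated genotypes probe set level gave 1779 and only the 2 groups 1184. The different response (291) had 537 among genes above the median, 89 at probe set level, 450 with trended and robust eBayes and 604 with array weights. Camera with an estimated correlation called 8, 8, 0, 1 and 3 lists in the 5 comparisons, in the order WT, D1D2KO, undifferentiated, differentiated and different response. In undifferentiated cells quantile normalization called 5 lists, genes above the median 2 and fry 6, and fry called 8 for the response. Dgat2 in undifferentiated cells was -0.50 after quantile normalization and no longer passed. The correlation of the responses was 0.959 above the median and 0.816 by Spearman. Fewer tested genes lower the adjustment and fewer samples the degrees of freedom. With only the 2 groups the undifferentiated count rose and the differentiated count fell, which reversed their order, so lost degrees of freedom do not account for both. The main fit shares 1 spread among the 4 groups. Mean correlations of a sample with its own group were 0.994 to 0.996 in differentiated and 0.997 in undifferentiated cells. The cause was not tested for this or the other alternatives. Without 1 sample, which leaves groups of at least 2, the counts ran from 5676 to 7152 (WT), 6480 to 7629 (D1D2KO), 339 to 1967 (undifferentiated), 1344 to 2822 (differentiated) and 159 to 449 (response). Dgat2 in undifferentiated cells ran from -0.49 to -0.45 and the correlation from 0.918 to 0.935. With the replicate number as a block, which by the rule above was taken to pair samples only in D1D2KO differentiation, the counts were 6932, 7460, 1922, 3070 and 254, and within genotype 6902, 7479, 1582, 2732 and 265. Of 508 called pairs of a named gene and a comparison 441 kept their call under every alternative run for single genes, and 0 changed direction. The 2-fold minimum and the probe set level were not run for single genes. Signal over background could not be assessed without detection calls.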

Other observations

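The lists of hypoxia-responsive, smooth muscle and cardiac muscle genes and the single genes named here were chosen after their values had been seen, apart from the muscle markers said here not to have been looked at before. The adipogenic regulators rose in both genotypes. Pparg, the receptor that troglitazone activates, rose by 3.97 (SE 0.10) in WT and 4.10 (SE 0.10) in D1D2KO cells, a difference of 0.13 (SE 0.14) that did not pass the limma test (adjusted p = 0.848). Cebpa rose by 2.31 and 2.84, and its difference of 0.53 (SE 0.14) did not pass either (adjusted p = 0.0760), although it was higher in differentiated D1D2KO cells by 0.46 (adjusted p = 0.00658). Of the lipogenic enzymes, Fasn rose by 2.99 and 2.84 and Acaca by 2.65 and 2.59, and neither passed the test between the genotypes after differentiation (Fasn -0.22, adjusted p = 0.178; Acaca -0.31, adjusted p = 0.179). The droplet coat gene Plin2 rose by 2.05 in both genotypes.

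Of 20 hypoxia-responsive genes 14 were lower in undifferentiated D1D2KO cells, with a median of -0.46, and 0 were higher. The list includes genes whose differences prompted it, so no test of it is given. The prolyl hydroxylase Egln3 stood at -1.47 (SE 0.12), Ndufa4l2 at -1.67 (SE 0.16), Bnip3 at -1.25 (SE 0.12), the mitochondrial protein Higd1a at -0.93, the carbonic anhydrase Car9 at -0.88 and the growth factor Vegfa at -0.49. Differentiation raised 18 of the 20 in WT and 19 in D1D2KO cells. Afterwards 1 gene was higher and 2 were lower in D1D2KO cells. Their median difference was then -0.10. The response differed by a median of 0.34, and 7 of the 20 genes passed. The list shares Pdk1 and Slc2a1 with the glucose list, so the 2 groups are not independent. No explanation of the lower values was tested.

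Of 10 smooth muscle markers not looked at before, 6 were lower in undifferentiated D1D2KO cells (median -0.43, camera adjusted p = 1.39e-07, and adjusted p = 0.0144 with an estimated correlation). In differentiated cells 8 were lower (median -0.66, adjusted p = 1.10e-11, and adjusted p = 0.00523 with an estimated correlation). Among the markers already seen, the potassium channel subunit Kcnmb1 stood at -1.74 and -1.84, the signalling regulator Rgs5 at -1.69 and -1.86, Synpo2 at -1.55 and -1.57, and the transcriptional coactivator Myocd at -1.11 and -0.47. The cardiac markers Myl2 (0.70) and Ttn (0.64), also already seen, were higher in undifferentiated cells. Of 15 cardiac markers not looked at before 4 were higher and 1, the troponin Tnnt2 (-0.63), was lower in undifferentiated cells (median 0.28, camera adjusted p = 0.0586). In differentiated cells 3 were higher and 1 lower (median 0.16, adjusted p = 0.0302, and adjusted p = 0.179 with an estimated correlation). The call of Myocd in differentiated cells ended without any 1 of the 3 WT differentiated samples or D1D2KO differentiated replicates 1 and 2 (adjusted p from 0.0538 to 0.131).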
